A study of Mus musculus with 8 samples.

How the data were processed

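Aortas of male C57BL/6J mice were profiled by RNA sequencing in 8 libraries, 4 from mice gavaged with saline (vehicle) and 4 from mice gavaged with colchicine at 200 µg per kg per day. Per the labels, the mice were 3 weeks old at the start, and all of them drank beta-aminopropionitrile (BAPN) at 1 g per kg per day over the 3 weeks of treatment. BAPN inhibits lysyl oxidase, the enzyme that crosslinks elastin and collagen, and is used to bring about aortic dissection in young mice. Colchicine binds tubulin, blocks the assembly of microtubules and is prescribed against inflammation. Aortas of mice without BAPN were not analysed here, so no value is set against a healthy aorta.

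Per the labels, RNA was isolated with a column kit and libraries were made with a SMARTer mRNA kit. The submitters' processing notes name the mouse genome build mm10. The aligner, the counting tool, the gene annotation and the use of strand are not given in the sources used here. Reads from overlapping or antisense genes, and reads shared by near-identical genes (the alpha and beta haemoglobin pairs, the alpha tubulins), could therefore have been split between genes in ways that cannot be checked. The authors deposited estimated counts per Ensembl gene and library, about 9% of them not whole, and TPM values per gene and library, per the file headers. In 1 TPM column the header lacked the unit, and its values had the same sum as those of the other 7. The table held 22063 genes, of which 4498 had no count in any library, and the 30 genes without a symbol held 5.89e-05% of the counts.

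Estimated counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 (R 4.3.3) for the 2 groups, which left 13431 genes for testing and left out 8632. Library totals were scaled with TMM factors (0.762 in vehicle 1, 0.987 to 1.08 in the other 7 libraries), and CPM denotes counts per 1e6 scaled counts. The edgeR quasi-likelihood test (two-sided) compared colchicine with vehicle with no covariate, and p-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. Log2 fold changes are colchicine minus vehicle and are printed with a standard error. This error was derived from the test, as the absolute change divided by the square root of its F statistic. The 15.4 to 18.5 M counts per library leave little counting error at high counts and a floor of 3 counts, 0.158 to 0.22 CPM per library, for a gene with none. Intervals and floors cover counting error only.

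Before the data were examined, 50 gene lists with 1027 different genes were fixed (1023 were in the table and 926 were tested), together with the main tests, the rule for named genes and most alternatives. Lists were tested on log2 CPM values from voom with camera (limma 3.58.1, inter-gene correlation preset at 0.01) and adjusted over the 50 lists. Camera was repeated with the correlation estimated per list, and fry was run beside it. Each list also got a level per library, the mean log2 CPM of its tested members with a prior count of 2. Levels were compared by an exact two-sided permutation test over the 70 assignments of the libraries, whose smallest possible p is 0.0286. Gene Ontology and pathway terms given in the deposited table were tested for over-representation among raised and among lowered genes by one-sided Fisher's exact tests, against the tested genes with any term of that kind and for terms of 10 to 500 genes.

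Named genes followed the fixed rule. It took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, without predicted genes, pseudogenes and receptor segments. It added up to 3 members of each described list past the threshold with the largest change, or the 2 with the smallest p where none passed, and always Lox, Acta2, Myh11, Eln, Col1a1, Col3a1, Mmp2, Mmp9, Spp1, Il1b, Nlrp3, Tubb5 and Tuba1b. Genes named outside the rule are said to be so, and some genes that the rule picked are not reported here. Gene positions, lengths and GC contents came from GENCODE M21 on GRCm38, the assembly that mm10 names, and 99.6% of the gene identifiers were found there.

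Other fits chosen before the data were examined were DESeq2 1.42.0, limma-voom, no TMM factors, RLE factors, other low-count filters, robust dispersion, the replicate number as a block, each library left out in turn, other thresholds, the level of brown adipocyte genes as a covariate and 1 surrogate variable (sva 3.50.0). Chosen after seeing the data were leaving out vehicle 1 and 4 together, the erythroid level as a covariate, a correction for GC content and transcript length, library totals without haemoglobin and mitochondrial genes, and limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1 in either group. Fits with libraries left out reran the low-count filter and tested 13512 to 13746 genes, so list members could differ from the main fit. On the real data DESeq2 was run without that filter and gave p-values for 17502 genes. The procedures were tested on simulated data with the means and totals of these libraries, in which 200 of 13431 genes were changed. edgeR recovered 75.8% of genes changed 4-fold, 19.4% of those changed 2-fold and 0% of those changed 1.5-fold, with 4.55% of its calls false, while DESeq2 gave 22.5% false calls. Simulated genes were independent and had the same dispersion in both groups. In the real data the median SD of log2 CPM was 0.393 in vehicle and 0.182 in colchicine libraries, and 34.4% of genes passed. The simulated rates therefore need not hold for the real data.

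No pair of libraries agreed within sampling noise (chi-square over degrees of freedom of 19.6 or more in every pair within a group), so all 8 were kept as separate samples. The labels do not state that each library came from 1 animal, and the p-values then measure only the spread between these samples.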

Results

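The study examined how colchicine changes gene expression in the aorta of mice in which BAPN brings about aortic dissection. RNA from 8 aorta libraries was sequenced, 4 from vehicle-treated and 4 from colchicine-treated mice, all of them given BAPN. Library totals were 17.9, 18.5, 17.5 and 15.4 M estimated counts in vehicle 1 to 4 and 16.8, 16.8, 18.3 and 16.9 M in colchicine 1 to 4.

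The first principal component of the 500 most variable genes held 78.9% of the variance and placed the 4 vehicle libraries between -69.3 and -9.9 and the 4 colchicine libraries between 28.5 and 45.1. Vehicle libraries differed more among themselves (Spearman correlation across genes of 0.905 to 0.956) than colchicine libraries did (0.982 to 0.991). The median standard deviation of log2 CPM over genes was 0.393 in the vehicle and 0.182 in the colchicine group (n = 4 each). Vehicle 1 and vehicle 4 stood apart in their content of red blood cell transcripts. The 4 haemoglobin genes made up 14.9% of the counts in vehicle 1 (exact 95% interval 14.92 to 14.96%) and 6.21% in vehicle 4 (6.198 to 6.223%), against 0.282% in vehicle 2, 0.0419% in vehicle 3 and 0.0914 to 0.318% in the colchicine libraries. Mitochondrially encoded genes made up 10.4% and 7.21% of the counts in vehicle 1 and 4, 2.26% and 3.48% in vehicle 2 and 3, and 4.4 to 4.87% in the colchicine libraries.

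**Figure D1:**
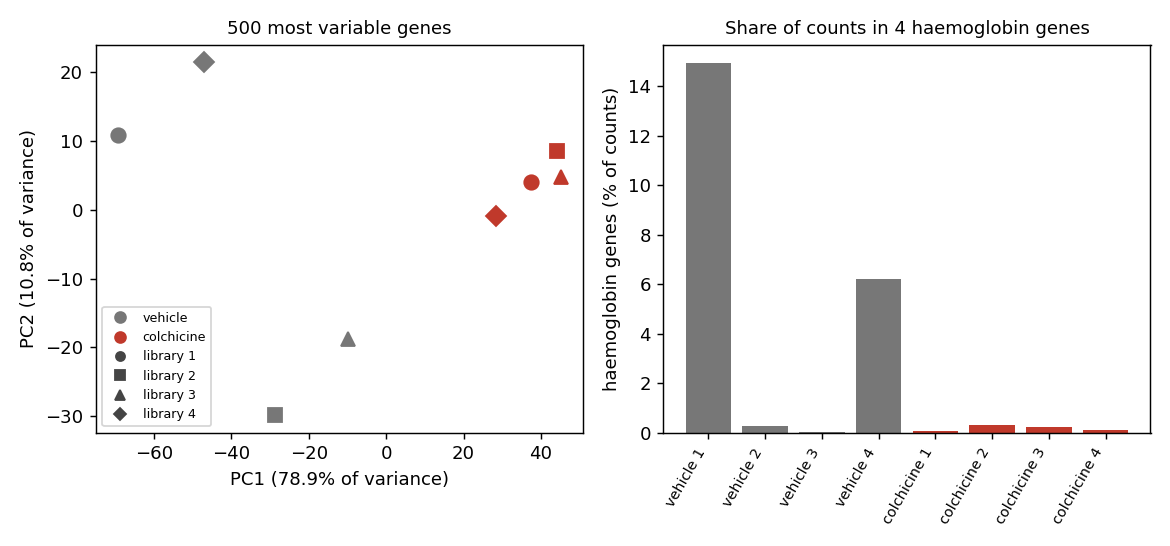
Left, the libraries on the first 2 principal components of log2 CPM of the 500 most variable genes (percent of variance on each axis), with grey symbols for vehicle, red for colchicine and 1 shape per library number; the groups separate on the first component. Right, the percent of each library's counts in 4 haemoglobin genes, 14.9% in vehicle 1, 6.21% in vehicle 4 and at most 0.318% in the other libraries.

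The comparison of colchicine with vehicle asked which aortic genes the drug changed during BAPN exposure. Inflammatory genes were far lower in the colchicine aortas. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, went from 259 ± 412 CPM in vehicle to 0.112 ± 0.102 CPM in colchicine libraries (SD, n = 4). Its vehicle mean came mostly from vehicle 1 and 4, the libraries rich in haemoglobin, and it did not pass with limma-voom (adjusted p = 0.118). In the chemokine and cytokine list 24 of 28 tested genes fell. Genes of the contractile apparatus of smooth muscle, the main cell type of the aortic media, were higher. Myocd, a coactivator that switches on contractile genes, went from 25.2 ± 15.9 to 116 ± 21.3 CPM, and 15 of 22 contractile genes rose while 0 fell. Lox, the target of BAPN, and the structural genes Eln, Col1a1 and Col3a1 did not pass the test.

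Of 13431 genes tested, 4619 (34.4%) differed between the groups, with 2342 raised and 2277 lowered by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Falls were larger than rises, since 712 genes fell and 89 rose by 2 or more on the log2 scale, and 187 fell and 0 rose by 4 or more. Raised genes made up 50.7% of the calls, and that share depended on the scaling, at 62.1% after a correction for GC content and transcript length (2748 raised, 1675 lowered) and 73.1% on log2 TPM values (2347 raised, 863 lowered). The median change over all genes was -0.03, 0.09 and 0.36 in these 3 fits. Without vehicle 1 and 4, the libraries rich in haemoglobin, 5570 genes passed, 2783 raised and 2787 lowered, and 3868 of them were among the 4619. Fewer genes passed without colchicine 1 (928 raised, 1449 lowered), colchicine 2 (898 raised, 1309 lowered) or colchicine 4 (1237 raised, 1685 lowered). Without vehicle 1, 1512 were raised and 2494 lowered. In 5245 genes (39.1%) the groups did not overlap, where chance gives 2.86%.

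The 10 genes with the largest falls were Il1b, Osm, Cxcl2, Il6, Cd300lf, S100a9, Ccl3, S100a8, Ccl4 and Cxcl3. All but Cd300lf, an inhibitory receptor of myeloid cells, encode secreted cytokines, chemokines or the calprotectin subunits of neutrophils. Il1b (ENSMUSG00000027398, GRCm38 chromosome 2, 129364570 to 129371139) fell by 11.08 ± 2.05 (adjusted p = 0.0071), and Il6, a cytokine of the acute phase response, fell by 9.47 ± 1.84 (adjusted p = 0.00789). Cxcl3, a neutrophil attractant (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), had 11775 counts over the vehicle and 2 over the colchicine libraries. Their ratio after scaling was 6260 with a 95% counting interval of 1730 to 51700 (adjusted p = 0.00833). Ccl4, an attractant of monocytes and T cells, had 1437 against 3 counts, a ratio of 509 with a counting interval of 174 to 2470 (adjusted p = 0.00735). Levels of these genes differed strongly among vehicle libraries, with Il1b at 869, 7.69, 10.2 and 150 CPM in vehicle 1 to 4, the highest in the haemoglobin-rich vehicle 1 and 4. All 10 also passed without vehicle 1 and 4 (adjusted p of 0.00395 to 0.0304), but their changes were smaller there, -6.37 to -1.96. None of the 10 passed with limma-voom (0.0562 to 0.352), where their changes were -9.26 to -5.87.

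The genes with the largest rises included Kctd16, Zbtb16, Sphkap, Slc24a4, Fmo2, Fam107a, Folh1, Hhip and Hif3a. Zbtb16, a zinc-finger transcription factor known as a target of glucocorticoids (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), rose from 9.56 ± 6.18 to 94.2 ± 10.8 CPM, a change of 3.30 ± 0.45 (adjusted p = 0.00413). Kctd16, a subunit of GABA-B receptors, rose by 3.33 ± 0.42 (adjusted p = 0.0039). Hhip, a hedgehog-binding protein, rose by 2.72 ± 0.62, and the flavin monooxygenase Fmo2 by 2.84 ± 0.54. Slc24a4 and Hif3a did not pass without colchicine 1 (adjusted p = 0.057 and 0.0638), and Hif3a did not pass without vehicle 1 and 4 (adjusted p = 0.055).

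Among the 50 fixed lists, 25 passed the camera test, 4 of them higher and 21 lower with colchicine. With an estimated correlation in place of the preset value 0 of the 50 passed, and the lowest adjusted p was 0.623, while fry passed 12 lists, 11 of them among the 25. Each camera call therefore rests on the preset correlation. Fry also passed dendritic cell, cytoskeleton, modulated smooth muscle, p53, cell death and chemokine genes. It passed interferon, matrix protease, glycolysis, tubulin and inflammasome genes as well (adjusted p of 0.00897 to 0.0476 for these 11). Lists that fry did not pass included contractile (adjusted p = 0.0539), calcium handling (0.051) and macrophage genes (0.063). Other ways of dividing the 8 libraries into groups of 4, some of which keep part of the real contrast, gave up to 30 passing lists. Divisions with as many vehicle as colchicine libraries on each side gave 8 to 25 passing lists and 0 passing genes. Camera at the preset correlation thus passed many lists without a contrast between the treatments, and its adjusted p-values can be too small. Chance can therefore not be excluded for the number of lists or, from camera alone, for a single list. The mean level of 24 lists was apart between the 4 vehicle and the 4 colchicine libraries, each with the smallest p of the exact permutation test, 0.0286, and an adjusted p of 0.0595.

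Of 28 chemokine and cytokine genes, 24 fell and 0 rose (27 changed when adjusted over the list alone, median -4.20, adjusted p = 8.18e-07, and adjusted p = 0.623 with an estimated correlation). The level of the list was 6.82, 3.85, 3.44 and 5.43 in vehicle 1 to 4 and 0.89 to 1.46 in the colchicine libraries. In the inflammasome and interleukin-1 list 10 of 18 members fell and 1 rose (13 changed when adjusted over the list alone, median -1.20, adjusted p = 0.00447, and adjusted p = 0.623 with an estimated correlation). Nlrp3, the sensor of the inflammasome that releases interleukin-1 beta (chromosome 11, 59541568 to 59566956), fell by 4.03 ± 0.78 from 14.4 ± 13.1 to 0.869 ± 0.292 CPM (adjusted p = 0.0078). The decoy receptor Il1r2 fell by 8.73 ± 1.76 and the receptor antagonist Il1rn, both of which restrain interleukin-1, by 8.32 ± 1.48. With limma-voom Nlrp3 (-3.34, adjusted p = 0.0557), Il1r2 (0.145) and Il1rn (0.123) did not pass. The member that rose was Nek7, a partner of Nlrp3, at 0.92, named after its value was seen. Interferon response genes fell in 23 of 28 cases (24 adjusted over the list alone, median -1.73, adjusted p = 4.83e-07, and adjusted p = 0.623 with an estimated correlation). They included the antiviral effectors Oas3, at -4.99 ± 0.73, Mx1, at -4.79 ± 0.48, and Rsad2, at -4.88 ± 0.92, the last of which did not pass with limma-voom (adjusted p = 0.0618). Over vehicle 1 to 4 the chemokine and inflammasome levels followed the order of the haemoglobin shares (inflammasome 5.08, 3.72, 3.41 and 4.595). The interferon level did not, since it was highest in vehicle 2 (5.07), a library with 0.282% haemoglobin counts.

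**Figure D2:**
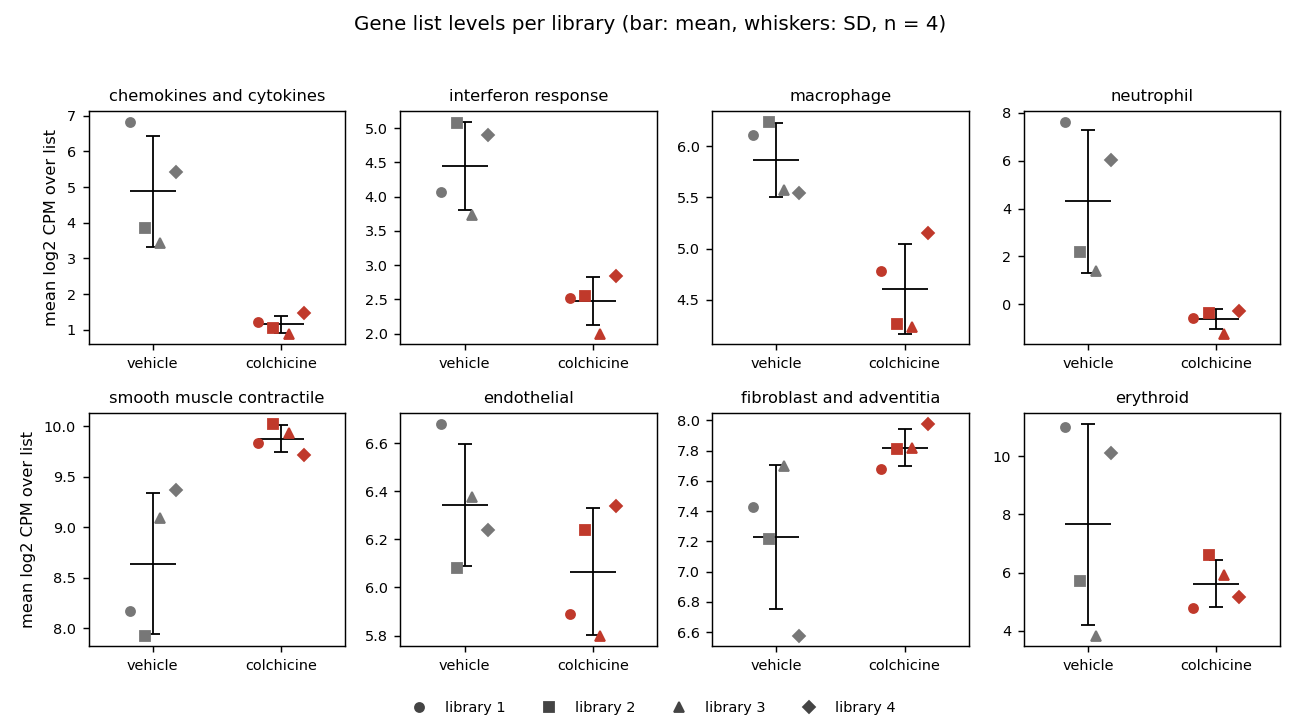
Mean log2 CPM over the tested members of 8 gene lists in each library, with grey symbols for vehicle, red for colchicine, 1 shape per library number, a bar for the mean and whiskers for the SD (n = 4). Chemokine, interferon, macrophage and neutrophil levels were lower in all 4 colchicine libraries than in any vehicle library and contractile levels were higher, while endothelial, fibroblast and erythroid levels overlapped.

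Markers of several blood cell types were also lower in the colchicine libraries. In the macrophage list 13 of 23 members fell and 4 rose (21 changed when adjusted over the list alone, median -1.58, adjusted p = 0.00962, and adjusted p = 0.623 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 fell by 4.71 ± 0.96 and the integrin Itgam by 3.70 ± 0.81, and the Fc receptor Fcgr1 stood at -3.996 ± 0.549. The 4 that rose, named after their values were seen, were Cd163 (2.18), Lyve1 (1.34), Mertk (1.24) and Cd209f (1.24), known as markers of macrophages resident in tissue. Dendritic cell and antigen presentation genes fell in 11 of 14 cases (11 adjusted over the list alone, median -2.11, adjusted p = 5.86e-05, and adjusted p = 0.623 with an estimated correlation), among them the homing receptor Ccr7 at -4.17 ± 0.43 and the lectin Cd209a at -3.21 ± 0.56. Adhesion molecules fell in 7 of 13 cases and rose in 1 (9 adjusted over the list alone, adjusted p = 0.0358, and adjusted p = 0.623 with an estimated correlation). The one that rose was the endothelial molecule Pecam1 (0.95), named after its value was seen. T and NK cell genes fell in 2 of 14 cases (2 adjusted over the list alone, median -1.03, adjusted p = 0.00335), led by the cytokine receptor Il7r at -4.16 ± 0.91. Among all tested genes 2277 of 13431 fell. The list levels overlapped, with 0.803 in colchicine 3 against 0.206 and 0.725 in vehicle 3 and 4 (exact permutation p = 0.0857). Without colchicine 3, where the low-count filter was rerun, the median was -2.29. Among genes with a CPM of 1 or more in at least 4 libraries the T and NK cell median was -0.65, and the list did not pass (adjusted p = 0.0936). B cell genes fell in 4 of 6 cases (4 adjusted over the list alone, median -3.52, adjusted p = 0.02), among them the co-receptor Cd22 at -3.62 ± 0.68. Both of these lists had an adjusted p = 0.623 with an estimated correlation. Platelet genes fell in 10 of 11 cases (10 adjusted over the list alone, median -4.38, adjusted p = 0.00763, and adjusted p = 0.623 with an estimated correlation). An example was the platelet chemokine Ppbp at -6.54 ± 1.45, which did not pass with limma-voom (adjusted p = 0.124). Camera did not pass for neutrophil genes (7 of 8 fell, 7 adjusted over the list alone, median -7.71, adjusted p = 0.0636) or erythroid genes (5 of 8 fell, 7 adjusted over the list alone, median -4.75, adjusted p = 0.105).

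The blood-rich vehicle 1 and 4 carried the highest levels of the neutrophil (7.61 and 6.01), platelet (5.82 and 5.02), B cell (3.83 and 3.56) and erythroid (11.002 and 10.117) lists, against 2.20 and 1.41, 1.92 and 1.85, 1.85 and 1.63, and 5.71 and 3.82 in vehicle 2 and 3. Without both of them 7 lists no longer passed, which were adhesion (median -1.09), B cell (-1.14), fibroblast (0.15), immediate early (-0.47), NRF2 (-0.54), oxidative phosphorylation (-0.06) and cholesterol (-0.18). Another 8 that did not pass with all 8 libraries passed then, which were the mitochondrially encoded list (0.91, adjusted p = 2.49e-05, with its sign changed), neutrophil (-2.51, adjusted p = 0.00412), cartilage (-2.59), white adipocyte (-1.44), lymph node (-1.42), collagens (-0.78), elastic fibre (-0.61) and heat shock (0.60). Some lists passed or failed with 1 library. Adhesion molecules did not pass without vehicle 1, vehicle 4, colchicine 1 or colchicine 3 (adjusted p of 0.0569 to 0.0959), nor B cell genes without vehicle 1 (0.0551), while neutrophil genes passed without vehicle 2, vehicle 3 or colchicine 3 (0.0097 to 0.0302) and, at a median of -3.54, with the erythroid level as a covariate (0.00187), and erythroid genes passed without vehicle 2 or 3 (0.025 and 0.0146). The haemoglobin genes Hbb-bs, Hba-a1 and Hbb-bt, whose reads may be split between near-identical copies, fell by 5.49 ± 1.66, 4.93 ± 1.58 and 5.13 ± 1.63. They did not pass without vehicle 1 (adjusted p of 0.0698 to 0.091) or without colchicine 1, 2, 3 or 4 (0.0758 to 0.106), Hba-a1 and Hbb-bt did not pass without vehicle 4 (0.0503 and 0.0501), and without vehicle 1 and 4 together Hba-a1 and Hbb-bt stood at 0.32 and 0.43.

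Smooth muscle contractile genes were higher, with 15 of 22 raised and 0 lowered (18 changed when adjusted over the list alone, median 1.04, adjusted p = 3.72e-06, and adjusted p = 0.623 with an estimated correlation). Myocd (chromosome 11, 65176561 to 65269989) rose by 2.21 ± 0.45 (adjusted p = 0.00883), and the integrin Itga8 by 2.03 ± 0.50 from 611 ± 425 to 2494 ± 326 CPM. Myh11, the smooth muscle myosin heavy chain (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372), rose by 1.71 ± 0.52 (adjusted p = 0.0331). Acta2, smooth muscle actin, was at 6854 ± 3740 CPM in vehicle and 13960 ± 3045 CPM in colchicine libraries, a change of 1.03 ± 0.43 that did not pass (adjusted p = 0.0914), although it passed without vehicle 4 (adjusted p = 0.0354), with DESeq2 (0.0281), with the brown adipocyte covariate (0.0295), after the GC and length correction (0.0481) and on log2 TPM (0.0335). Itga8 did not pass without colchicine 1 or 2 (0.0515 and 0.0551), nor Myh11 without vehicle 1, vehicle 3, or colchicine 1, 2, 3 or 4 (0.0521 to 0.0942). The vehicle libraries with the lowest contractile levels were vehicle 1 (8.17) and vehicle 2 (7.93), and those with the highest were vehicle 3 (9.09) and vehicle 4 (9.37), so haemoglobin content did not order them. Calcium handling and vascular tone genes rose in 12 of 26 cases and fell in 1 (15 adjusted over the list alone, median 1.07, adjusted p = 0.00065, and adjusted p = 0.623 with an estimated correlation). Examples were the cGMP phosphodiesterase Pde5a (1.89 ± 0.40), the guanylate cyclase subunit Gucy1b1 (1.79 ± 0.40) and the potassium channel subunit Abcc9 (1.77 ± 0.32), and the member that fell, named after its value was seen, was the potassium channel Kcna5 (-1.54). Cytoskeleton genes linked to SMAD, YAP and SRF rose in 12 of 27 cases and fell in 3 (16 adjusted over the list alone, median 0.53, adjusted p = 0.0171, and adjusted p = 0.623 with an estimated correlation). Ankrd1 fell by 1.65 but did not pass without colchicine 1, 2, 3 or 4 (adjusted p of 0.0502 to 0.0886) and stood at -0.93 without vehicle 1. Actg1 (-1.24) and Actb (-1.06), named after their values were seen, also fell. The list did not pass after the GC and length correction.

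**Figure D3:**
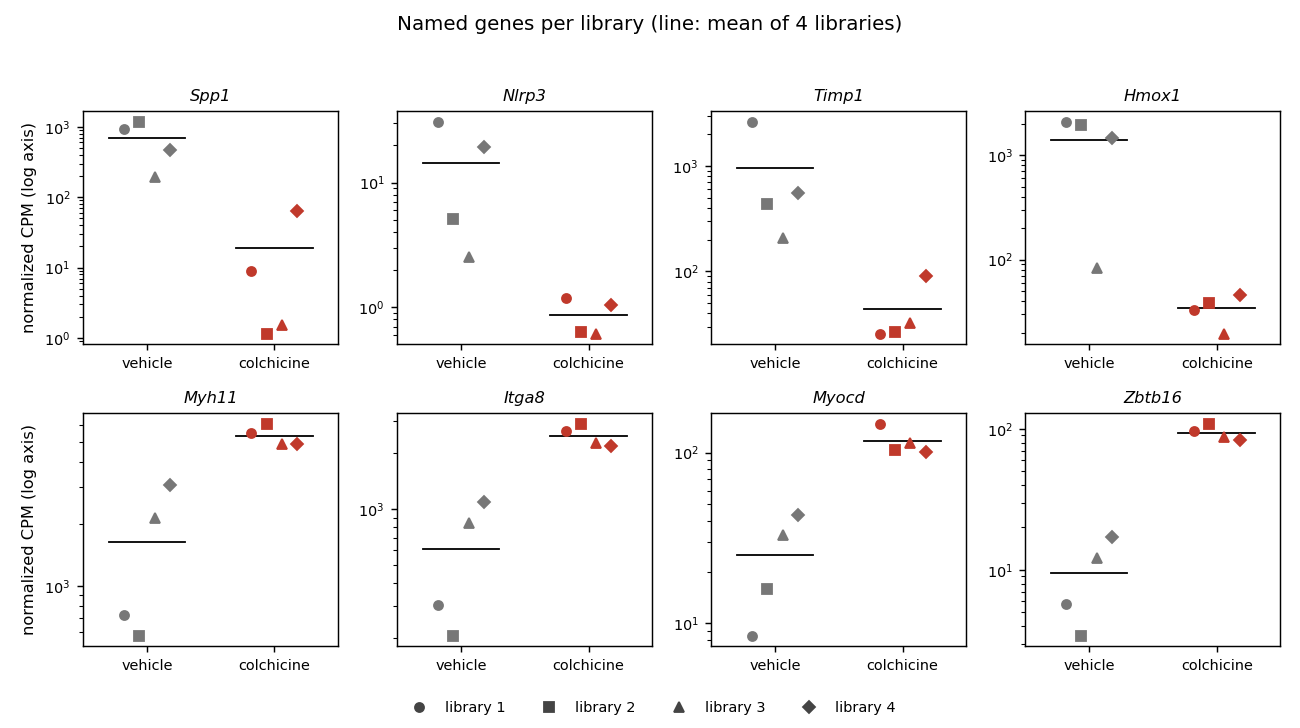
CPM (log axis) of 8 named genes in each library, with grey symbols for vehicle, red for colchicine, 1 shape per library number and a line at the mean of 4 libraries. Spp1, Nlrp3, Timp1 and Hmox1 were lower in every colchicine library than in any vehicle library, and Myh11, Itga8, Myocd and Zbtb16 were higher.

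Genes of modulated smooth muscle, which is smooth muscle that has left the contractile state, were lower in 10 of 20 cases and higher in 2 (15 adjusted over the list alone, median -1.24, adjusted p = 0.000811, and adjusted p = 0.623 with an estimated correlation). Spp1, osteopontin (chromosome 5, 104435118 to 104441050), fell by 5.17 ± 1.32 from 685 ± 438 to 19 ± 30.5 CPM (adjusted p = 0.0187), with 64.5 CPM in colchicine 4 against 1.15 to 8.9 CPM in the other 3 colchicine libraries, and did not pass without colchicine 1 (adjusted p = 0.0606). The protease inhibitor Timp1 fell by 4.44 ± 0.87 and the collagen Col8a1 by 4.66 ± 1.03. Col8a1 stood at 9.35 CPM in vehicle 4, below all 4 colchicine libraries (10.1 to 24.8 CPM), and did not pass with limma-voom (adjusted p = 0.0518) or on log2 TPM (0.0569). The 2 that rose were Klf4 (0.61), a transcription factor of smooth muscle modulation, and Vim (0.62), vimentin, both named after their values were seen. Many of these genes are also expressed by macrophages and fibroblasts, and the macrophage list was lower in the same libraries, by 1.26 on the level scale.

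Matrix-degrading enzymes and their inhibitors fell in 13 of 30 cases and rose in 0 (16 adjusted over the list alone, median -0.78, adjusted p = 0.02, and adjusted p = 0.623 with an estimated correlation), though the list did not pass without vehicle 1 (adjusted p = 0.06) and its median was -0.33 without vehicle 2. The aggrecanase Adamts4 fell by 4.86 ± 0.54 and the macrophage elastase Mmp12 by 4.79 ± 1.01. The gelatinase Mmp9 fell by 4.78 ± 1.16 from 140 ± 137 to 5.1 ± 3.77 CPM (adjusted p = 0.0153), but its groups overlapped, with 3.95 CPM in vehicle 3. Mmp9 did not pass without colchicine 2 (0.0525), without vehicle 1 and 4 (0.0828), with limma-voom (0.114) or with the erythroid covariate (0.0725). The other gelatinase, Mmp2, stood at -0.80 ± 0.55 (adjusted p = 0.276). Lox (chromosome 18, 52516067 to 52529867) stood at -0.37 ± 0.35 (adjusted p = 0.427), Eln at 0.17 ± 0.53 (0.81), Col1a1 at -0.86 ± 0.69 (0.343) and Col3a1 at -0.52 ± 0.55 (0.479). Vehicle 4 held the lowest Col1a1 (2527 CPM), Col3a1 (3896 CPM), Mmp2 (199 CPM) and Lox (345 CPM) of all 8 libraries, and without it Lox at -0.64 (adjusted p = 0.0406) and Mmp2 at -1.14 (adjusted p = 0.0339) passed and Col3a1 stood at -0.86. Without vehicle 2, which held the highest Col1a1 (35580 CPM), Col1a1 stood at 0.14, Col3a1 at 0.07 and Mmp2 at -0.15. Eln was negative without vehicle 1 (-0.10), vehicle 4 (-0.09) or colchicine 3 (-0.15), and stood at 0.33, 0.50, 0.26 and 0.33 without vehicle 2, vehicle 3, colchicine 2 and colchicine 4. Without vehicle 1 and 4 together Col1a1 (-1.62, adjusted p = 0.0171), Col3a1 (-1.12, adjusted p = 0.0185) and Mmp2 (-1.41, adjusted p = 0.0104) passed.

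Lists of structural matrix did not pass with all 8 libraries. Without vehicle 1 and 4 the collagen list (median -0.78, adjusted p = 0.00281) and the elastic fibre list (median -0.61, adjusted p = 0.00801) did. Collagens and collagen processing had 6 lower and 1 higher of 29 (6 adjusted over the list alone, median -0.48, adjusted p = 0.583). Examples were Col11a1 at -6.07 ± 1.45 and Col12a1 at -3.66 ± 0.98. Vehicle 4 went the other way, with 0.984 CPM of Col11a1, below all 4 colchicine libraries (2.44 to 3.4 CPM), and 47.8 CPM of Col12a1, inside their range (30 to 65.1 CPM). With limma-voom neither gene passed (0.245 and 0.0507), nor did they on log2 TPM (-3.23 and -2.55, adjusted p = 0.0672 and 0.0593). The list passed without vehicle 4 at a median of -0.70 (adjusted p = 0.0365), against 0.09 without vehicle 2. Col11a1 did not pass without colchicine 2 (adjusted p = 0.0506), nor Col12a1 without colchicine 1, 2 or 3 (0.0573 to 0.0669), and Col12a1 fell by only 1.98 without vehicle 2. Elastic fibre genes had 3 lower and 1 higher of 22 (4 adjusted over the list alone, median -0.34, adjusted p = 0.688). Fbn2 fell by 4.41 ± 1.04, but its 0.308 CPM in vehicle 4 lay below all 4 colchicine libraries (0.517 to 1.44 CPM). It did not pass with limma-voom (adjusted p = 0.232) or on log2 TPM (-1.43, adjusted p = 0.0748). The list median was 0.04 without vehicle 2 and -0.54 without vehicle 4. Proteoglycan genes had 2 higher and 3 lower of 16 (5 adjusted over the list alone, median 0.32 and mean -0.35, adjusted p = 0.47). The hyaluronan synthase Has1 fell by 4.32 ± 0.97 and did not pass with limma-voom (adjusted p = 0.0678). The list median was 0.13, 0.16 and 0.20 without vehicle 1, vehicle 4 and colchicine 1. TGF-beta response genes had 3 higher and 7 lower of 23 (12 adjusted over the list alone, median -0.01, adjusted p = 0.583). Examples were the ligand Tgfb2 at 1.505 ± 0.265 and Junb at -2.36 ± 0.58, which did not pass without vehicle 1 and 4 (adjusted p = 0.0681). The list median changed sign without vehicle 3 (0.05) or colchicine 1 (0.01) and was -0.17, -0.06, -0.16, -0.17 and -0.04 without vehicle 1, vehicle 2, vehicle 4, colchicine 3 and colchicine 4. On log2 TPM the collagen and elastic fibre medians were 0.28 and 0.215, or -0.07 and -0.14 relative to all genes, and after the GC and length correction the proteoglycan median was -0.04.

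Among other cell types of the wall, fibroblast and adventitia genes rose in 6 of 20 cases and fell in 0 (6 adjusted over the list alone, median 0.32, adjusted p = 0.013, and adjusted p = 0.623 with an estimated correlation), led by Abca8a at 2.01 ± 0.38 and the scavenger receptor Scara5 at 1.43 ± 0.32. The list did not pass without vehicle 4 (median 0.11, adjusted p = 0.169), which had the lowest level, 6.58 against 7.22 to 7.70 in vehicle 1 to 3. Endothelial genes went both ways, 5 higher and 4 lower of 19 (11 adjusted over the list alone, median -0.33, adjusted p = 0.442), with a median of 0.17 both after the GC and length correction and on log2 TPM (-0.19 relative to all genes). The growth factor receptor Kdr fell by 2.82 ± 0.34 and the guidance receptor Robo4 by 3.60 ± 0.36, whereas the phosphatase Ptprb rose by 1.43 ± 0.27.

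Lists of the early stress response, cell death, growth arrest and oxidative stress passed as lower. Immediate early genes fell in 12 of 25 cases and rose in 1 (17 adjusted over the list alone, median -1.02, adjusted p = 0.00113). Examples were the cytokine signalling inhibitor Socs3 at -3.61 ± 0.55 and the transcription factor Egr2 at -2.79 ± 0.42. Cell death genes fell in 13 of 19 cases and rose in 1 (14 adjusted over the list alone, median -0.77, adjusted p = 0.000741). Examples were the necroptosis kinase Ripk3 at -3.01 ± 0.38 and its activator Zbp1 at -3.74 ± 0.52. Leukocyte markers fell in the same libraries, by 1.26 on the level scale for the macrophage and 1.94 for the dendritic cell list. Genes of p53 and growth arrest fell in 9 of 19 cases and rose in 2 (11 adjusted over the list alone, median -0.95, adjusted p = 0.0119). Examples were Pmaip1 at -3.48 ± 0.53 and the stress cytokine Gdf15 at -2.46 ± 0.45. Oxidative stress genes controlled by NRF2 fell in 11 of 24 cases and rose in 1 (15 adjusted over the list alone, median -0.83, adjusted p = 0.0326). All 4 lists had an adjusted p = 0.623 with an estimated correlation. Members that rose, named after their values were seen, were Klf4 (0.61), the survival gene Bcl2 (1.45), the p53 targets Trp53inp1 (2.19) and Sesn1 (0.93), and Gstm1 (1.12). The haem-degrading enzyme Hmox1 fell by 5.34 ± 0.88 from 1386 ± 908 to 34.2 ± 11.3 CPM (adjusted p = 0.00556), with 2072, 1934, 82.6 and 1457 CPM in vehicle 1 to 4, so that vehicle 2 with few haemoglobin counts was about as high as vehicle 1. The cystine transporter Slc7a11 fell by 6.15 ± 1.11 and did not pass with limma-voom (adjusted p = 0.112). The NRF2 list did not pass without vehicle 1, vehicle 4 or colchicine 2 (adjusted p of 0.0508 to 0.125). Glycolysis and hypoxia genes fell in 13 of 23 cases (14 adjusted over the list alone, median -1.002, adjusted p = 6.96e-05, and adjusted p = 0.623 with an estimated correlation). The lactate transporter Slc16a3 fell by 2.30 ± 0.46. After the GC and length correction the medians were smaller, at -0.62 for immediate early, -0.56 for p53, -0.53 for NRF2 and -0.62 for glycolysis genes. Relative to all genes in that fit they were -0.71, -0.65, -0.62 and -0.71. On log2 TPM they were -0.78, -0.79, -0.70 and -0.72 relative to all genes.

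Ribosomal protein genes fell in 17 of 40 cases (19 adjusted over the list alone, median -0.61, adjusted p = 6.74e-07, and adjusted p = 0.623 with an estimated correlation). Rps19 fell by 1.00 ± 0.26 but did not pass without colchicine 1 (adjusted p = 0.0529) or on log2 TPM (adjusted p = 0.0971), and Rplp2 fell by 1.07 ± 0.29 but did not pass without colchicine 1, 2, 3 or 4 (0.0504 to 0.0598) or after the GC and length correction (-0.24, adjusted p = 0.324). Nuclear-encoded oxidative phosphorylation genes fell in 10 of 37 cases (9 adjusted over the list alone, median -0.43, adjusted p = 5.32e-05, and adjusted p = 0.623 with an estimated correlation). The cytochrome oxidase subunit Cox5a fell by 1.22 ± 0.29. After the correction for GC content and transcript length the medians of these 2 lists stood at 0.05, and neither passed. Cholesterol synthesis genes fell in 3 of 19 cases (2 adjusted over the list alone, median -0.31, adjusted p = 0.0358, and adjusted p = 0.623 with an estimated correlation). An example was Mvd at -1.35 ± 0.31. The list did not pass without vehicle 3, vehicle 4 or colchicine 2 (0.0661 to 0.0918). On log2 TPM the median of the cholesterol list was 0.11 and that of oxidative phosphorylation 0.025, or -0.25 and -0.33 relative to all genes on that scale.

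Tubulins, the protein family colchicine binds, fell in 6 of 17 cases and rose in 0 (6 adjusted over the list alone, median -0.63, adjusted p = 0.00685, and adjusted p = 0.623 with an estimated correlation). Tubb3 fell by 2.48 ± 0.42 and the platelet form Tubb1 by 4.71 ± 1.08, while Tuba1b, which has close paralogs, fell by 0.63 ± 0.19 (adjusted p = 0.0343) but did not pass without vehicle 2, colchicine 1, colchicine 2 or colchicine 4 (0.0584 to 0.091), without TMM factors (0.053), with the erythroid covariate (0.0613), after the GC and length correction (-0.11, adjusted p = 0.574) or on log2 TPM (-0.22, adjusted p = 0.514). Tubb1, also a member of the platelet list, did not pass with limma-voom (0.105). The platelet and macrophage lists were lower in the same libraries, by 3.16 and 1.26 on the level scale. Tubb5 stood at -0.55 ± 0.21 (adjusted p = 0.0725) and passed without vehicle 4 (0.0237), without vehicle 1 and 4 (0.0221), with DESeq2 (0.0302), with the brown adipocyte covariate (0.0216) and with 1 surrogate variable (0.0463). After the GC and length correction the list median was -0.18, and the list did not pass. Genes of microtubule-associated proteins had 8 higher and 4 lower of 30 (12 adjusted over the list alone, median 0.15, adjusted p = 0.348). Examples were Map1b at 1.61 ± 0.34 and Clip1 at 1.59 ± 0.21. The list had a median of -0.02 without vehicle 2 and 0.23 without vehicle 4. It passed fry as higher (adjusted p = 0.0213). Its level was higher in all colchicine libraries than in any vehicle library (exact permutation p = 0.0286, adjusted p = 0.0595). Proliferation genes fell in 3 of 30 cases (3 adjusted over the list alone, median -1.04, adjusted p = 0.013, and adjusted p = 0.77 with an estimated correlation), with levels of 3.58, 4.54, 4.23 and 1.83 in vehicle 1 to 4 and of 1.93 to 3.58 in the colchicine libraries. That list did not pass without vehicle 1, vehicle 2, vehicle 3, colchicine 1 or colchicine 2 (0.053 to 0.101).

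Further lists did not pass. NADPH oxidase genes fell in 5 of 9 cases and rose in 1 (7 adjusted over the list alone, median -1.605, adjusted p = 0.0555). Examples were the leukocyte subunits Ncf4 and Ncf1 at -3.45 and -2.98 and Nox4, the form of vessel wall cells, at 1.58, the last named after its value was seen. The list passed without vehicle 3 (adjusted p = 0.0186). Genes of the unfolded protein and integrated stress response fell in 4 of 27 cases and rose in 2 (4 adjusted over the list alone, median -0.355, adjusted p = 0.0975). An example was the asparagine synthetase Asns at -2.36. This list passed without vehicle 3 (0.0182) or colchicine 3 (0.0295). Heat shock genes rose in 2 of 16 cases and fell in 1 (3 adjusted over the list alone, median 0.246, adjusted p = 0.296). This list had medians of 0.11 and 0.14 without vehicle 3 and colchicine 3. It passed as higher after the GC and length correction (0.65, adjusted p = 0.0477), with the erythroid covariate (0.46, adjusted p = 0.0164) and without vehicle 1 and 4 (0.60, adjusted p = 0.00747). Autophagy and lysosome genes fell in 4 of 21 cases and rose in 1 (5 adjusted over the list alone, median -0.15, adjusted p = 0.346). This list had a median of 0.02 without vehicle 2. Fatty acid oxidation genes fell in 5 of 28 cases (3 adjusted over the list alone, median -0.09, adjusted p = 0.441). An example was Acads at -0.69, which did not pass after the GC and length correction (-0.27, adjusted p = 0.187) or on log2 TPM (-0.26, adjusted p = 0.564). The oxidation list had a median of 0.07 without vehicle 4 and of -0.33, -0.16, -0.33 and -0.03 without vehicle 1, vehicle 2, colchicine 1 and colchicine 3. Fatty acid synthesis genes fell in 3 of 18 cases (1 adjusted over the list alone, median -0.31, adjusted p = 0.337). An example was Srebf1 at -0.76, which did not pass on log2 TPM (-0.33, adjusted p = 0.431). This list passed without vehicle 1 (median -0.63, adjusted p = 0.0292), against a median of -0.06 without vehicle 4. None of the 13 mitochondrially encoded genes passed (0 adjusted over the list alone, median -0.35, adjusted p = 0.917), and their median was 0.13, -0.65 and -0.60 without vehicle 1, vehicle 2 and vehicle 3. On log2 TPM, relative to all genes, the medians of the stress response, autophagy, oxidation, synthesis and mitochondrially encoded lists were -0.25, -0.08, -0.03, -0.14 and 0.08.

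Lists of cell types found around the aorta did not pass either. White adipocyte genes fell in 3 of 17 cases (1 adjusted over the list alone, median -1.22, adjusted p = 0.0877). An example was the fatty acid carrier Fabp4 at -1.88. This list passed without vehicle 1 (0.00325) or colchicine 1 (0.0418), against a median of -0.62 without vehicle 3. Brown adipocyte genes fell in 1 of 17 cases (0 adjusted over the list alone, median 0.209 and mean -0.26, adjusted p = 0.688). This list had medians of -0.32 and -0.01 without colchicine 1 and vehicle 2, of 0.41 without vehicle 4, and of 0.03, 0.13 and 0.10 without vehicle 1, vehicle 3 and colchicine 2. Skeletal muscle genes rose in 1 and fell in 1 of 10 cases (0 adjusted over the list alone, median -0.60, adjusted p = 0.598). This list had medians of -0.08 and -1.04 without vehicle 1 and colchicine 1. Cardiac muscle genes rose in 1 and fell in 1 of 16 cases (1 adjusted over the list alone, median -1.98, adjusted p = 0.124). An example was Myoz2 at 1.38. This list passed without vehicle 2 (0.00806), against a median of -1.10 without vehicle 1. Schwann cell genes rose in 2 and fell in 1 of 11 cases (2 adjusted over the list alone, median 0.16, adjusted p = 0.704). An example was myelin basic protein Mbp at -1.44, which did not pass on log2 TPM (-0.70, adjusted p = 0.0738). The Schwann cell median was negative in all 8 fits with 1 library left out. It was -0.18, -0.04, -0.04 and -0.69 without vehicle 1 to 4, and -0.01, -0.44, -0.19 and -0.53 without colchicine 1 to 4. With DESeq2 it was -0.39. The low-count filter was rerun in the 8 fits, which tested 13512 to 13649 genes, and was not used with DESeq2. The members could therefore differ from the 11 above, so the change of sign need not come from the library left out. Mesothelial and epithelial genes fell in 2 of 12 cases (2 adjusted over the list alone, median -0.53, adjusted p = 0.124). An example was the cadherin Cdh1 at -4.85. This list passed without vehicle 2 (0.00806), against medians of -0.06 and -0.94 without vehicle 3 and colchicine 1. Lymph node and lymphatic genes fell in 4 of 8 cases and rose in 1 (5 adjusted over the list alone, median -1.15, adjusted p = 0.0975). An example was the lymphatic glycoprotein Pdpn at -3.35. The lymphatic list passed without vehicle 4 (0.0142).

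Annotated terms in the deposited table gave 223 enriched terms. Among lowered genes, the process with the lowest adjusted p was immune system process (102 of 246 genes lowered, 39.4 by chance, adjusted p = 7.02e-19), followed by inflammatory response (62 of 133, 21.3 by chance, adjusted p = 4.16e-14). Cytokine-cytokine receptor interaction led the lowered pathways, with 85 of 159 genes against 32.8 by chance (adjusted p = 6.9e-18), and 63 of 185 ribosome genes were lowered (31.7 by chance, adjusted p = 2.58e-06). The ribosome term was not tested after the GC and length correction, where the ribosomal protein list did not pass camera (median 0.05, adjusted p = 0.662). Among raised genes, vascular smooth muscle contraction had 34 of 95 (15.4 by chance, adjusted p = 0.0004), cGMP-PKG signalling 42 of 133 (21.6 by chance, adjusted p = 0.000573) and the anchoring junction component 92 of 291 (50.4 by chance, adjusted p = 6.68e-07), all by one-sided Fisher's exact tests. Such tests treat genes as independent, so these p-values can be too small. Estimated correlations between list members were 0.452 for chemokine, 0.578 for interferon and 0.951 for ribosomal protein genes. By the same tests, raised terms also included the glutamatergic synapse component (121 of 464, 80.4 by chance, adjusted p = 0.000122). The axon guidance pathway was another (44 of 153, 24.8 by chance, adjusted p = 0.00236). Changes went up with transcript length (Spearman 0.35), and the raised terms were not tested after the GC and length correction.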

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

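All tests in this part were chosen after the result in question was seen, except for the counts over other divisions of the libraries.

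Chemokine and cytokine genes, and neutrophil genes, were lower in the colchicine libraries, and the vehicle libraries with the most haemoglobin had the highest levels. Blood in vehicle 1 and 4 could raise such genes. The lower of vehicle 2 and 3 still lay above the highest colchicine level by 1.97 for the chemokine and 1.7 for the neutrophil list. Blood in vehicle 1 and 4 is therefore not the whole cause. Which aortas were dissected is not given in the sources used here. Blood from a dissected wall and blood carried over at collection can therefore not be told apart. Nor can effects of dissection on these genes be told apart from effects of the drug. Fewer leukocytes in the tissue could also lower chemokine transcripts, and the macrophage list fell by 1.26 on the level scale. Lower expression per cell and fewer cells cannot be told apart, because whole tissue gives no count of cells and macrophage markers can themselves change with activation.

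Contractile genes could be higher because leukocytes and blood diluted the vessel wall in the vehicle libraries. Relative to the endothelial list the contractile list rose by 1.51 (exact permutation p = 0.0286), and relative to the fibroblast list by 0.65 with overlapping groups (exact permutation p = 0.229). Dilution and a rise within smooth muscle cannot be told apart, because the answer depended on which wall cells served as the reference and on 1 library. Contractile minus fibroblast levels were 0.75, 0.71, 1.39 and 2.79 in vehicle 1 to 4 and 1.74 to 2.21 in the colchicine libraries, so the overlap came from vehicle 4 alone. A bias by GC content and transcript length does not account for it, since the list median was 1.24 after the correction.

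Ribosomal protein genes were lower, and so were oxidative phosphorylation genes, and both are short transcripts. Other genes of the same length and GC content predicted medians of -0.76 and -0.51, against the observed -0.61 and -0.43, so the bias may account for both falls in full. Across 13414 genes the change correlated with length (Spearman 0.35) and GC content (-0.31), but whether this stems from the libraries or the biology was not tested. Leaving haemoglobin and mitochondrial transcripts out of the totals gave a ribosomal median of -0.63, but it moved the medians of 48 lists by only 0.03 (median), so it could not decide whether they played a part.

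Over the 35 divisions of the 8 libraries into groups of 4, only 1, the real one, gave 4619 or more changed genes, and the highest other count was 0. The exact p of that result is 0.0286, the smallest possible, and edgeR gave up to 1989 genes at unadjusted p under 0.05 in the other divisions. For the 25 passing lists, 6 of 35 divisions gave as many or more, and the highest other count was 30, so chance cannot be excluded for that number. The division with 30 had vehicle 1, 3 and 4 and colchicine 1 on 1 side and so kept part of the real contrast. Even divisions, with as many vehicle as colchicine libraries on each side, gave 8 to 25 lists and 0 genes. The one with 25 lists had vehicle 1 and 2 and colchicine 2 and 4 on 1 side. Camera at the preset correlation thus passed many lists where the treatments were balanced.

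Single libraries stood away from the other 3 of their group, where chance picks out about 1 in 20 groups. This held for 1 of 14 library measures, 8 of 100 list levels and 14 of 316 gene groups. In colchicine 3 the 10 most abundant genes took 15.5% of the counts (11.7 to 12.2% in the others). In colchicine 1 the levels of the brown adipocyte (3.75, others 2.67 to 2.76), fatty acid oxidation (5.6, others 4.97 to 5.06), circadian clock (5.47, others 5.11 to 5.14) and glucocorticoid response (6.19, others 5.67 to 5.7) lists were high. In colchicine 2 the B cell level was -1.25 (others 0.472 to 0.587) and the ribosomal protein level 8.78 (others 8.62 to 8.64). In vehicle 4 the dendritic cell level was 3.81 (others 4.13 to 4.2) and the lymph node level 3.27 (others 4.45 to 4.63).

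Among named genes, log2 CPM values stood apart as follows. Vehicle 4 had -0.719 for the hypertrophic cartilage collagen Col10a1 (others 7.41 to 8.3), and vehicle 3 had 6.37 for Hmox1 (others 10.5 to 11) and 1.12 for Pmaip1 (others 2.45 to 2.69). Vehicle 2 had -0.85 for Myl1 (others 1.33 to 1.78), and vehicle 1 had 5.54 for Slc25a1 (others 6.16 to 6.24). Colchicine 1 had 7.26 for Mt2 (others 5.47 to 5.7), 3.21 for Egln3 (others 2.61 to 2.68) and 5.17 for Ezr (others 4.68 to 4.75). Colchicine 2 had -2.12 for Col2a1 (others 0.561 to 0.962), 7.23 for Rplp2 (others 7.01 to 7.03) and 0.0487 for S100a8 (others -1.55 to -1.35). Colchicine 3 had -3.11 for Ccl4 (others -2.55 to -2.53), but Ccl4 had only 3 counts over all colchicine libraries, so this difference lies at the floor. Colchicine 4 had 1.98 for Kctd16 (others 3.1 to 3.18) and 5.42 for Emilin2 (others 4.83 to 4.91).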

How the results depend on the processing

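The fits without vehicle 1 and 4, with the erythroid level, with the GC and length correction, without haemoglobin and mitochondrial genes in the totals, and on log2 TPM were chosen after the result was seen. The other fits were chosen before the data were examined. Of 4619 changed genes (2342 raised, 2277 lowered), DESeq2 gave 5762, limma-voom 4299, no TMM factors 3766, RLE factors 4591, no low-count filter 4480, a CPM of 1 or more in at least 4 libraries 4520, robust dispersion 4594, the brown adipocyte covariate 5237 and 1 surrogate variable 5723. Stricter thresholds gave 1404 (603 raised, 801 lowered) at an adjusted p under 0.01 and 2337 (926 raised, 1411 lowered) with an absolute log2 fold change of 1 or more, and a threshold of 0.10 gave 6151. The erythroid covariate gave 4052, the GC and length correction 4423, totals without haemoglobin and mitochondrial genes 4599, and log2 TPM 3210 (2347 raised, 863 lowered). Leaving out 1 library gave 2207 to 5058 changed, 898 to 2420 raised and 1309 to 2642 lowered genes, and 22 to 28 passing lists against 25. Camera with an estimated correlation passed 0 lists and fry 12. The mitochondrially encoded list, at -0.35 and not passing, stood at 0.91 without vehicle 1 and 4 (adjusted p = 2.49e-05) and at 0.52 with the erythroid covariate (adjusted p = 0.0256). Signs also changed for Cox5b (0.06), Etfb (0.24) and Rplp1 (0.25) after the GC and length correction, and for Hba-a1 (0.32) and Hbb-bt (0.43) without vehicle 1 and 4. Of 149 named genes that passed, 98 passed in all 8 fits with 1 library left out, 103 with limma-voom, 130 without vehicle 1 and 4, 120 after the GC and length correction and 104 on log2 TPM. Further lists that changed their call had these medians. T and NK cell genes did not pass with a CPM of 1 or more in at least 4 libraries (-0.65, adjusted p = 0.0936), nor did adhesion (-1.08), NRF2 (-0.77) and cholesterol genes (-0.32) with the brown adipocyte covariate. Cholesterol genes also did not pass without TMM factors (-0.21) or low-count filter (-0.29), nor with the erythroid covariate (-0.22), where fibroblast genes did not pass either (0.24). Neutrophil genes passed without TMM factors (-7.42), without filter (-6.38), with the stricter filter (-8.52), 1 surrogate variable (-7.20), the GC and length correction (-7.09) and the erythroid covariate (-3.54). NADPH oxidase genes passed without TMM factors (-1.44), with 1 surrogate variable (-1.62), the correction (-1.25) and the erythroid covariate (-1.22), and erythroid genes with 1 surrogate variable (-3.73). Lymph node genes passed without filter (-1.51), with the correction (-1.08) and the erythroid covariate (-1.42), and white adipocyte genes with that covariate (-1.61). The cause of these differences was not tested. Fits with pseudocounts of 0.1 and 5 were meant for a file without counts and were not run, since the file held counts. Called lists whose median moved by over 1.5 times on log2 TPM, where adding 1 shrinks changes of low genes, had these values relative to all genes. They were chemokines -2.55, platelet -2.38, B cell -1.50, interferon -1.44, macrophage -1.27, modulated smooth muscle -1.01, adhesion -0.94, T and NK cell -0.93, proliferation -0.81, cell death -0.69, matrix proteases -0.56, tubulins -0.52, ribosomal -0.48, fibroblast 0.45, cytoskeleton 0.48 and contractile 1.26. After the GC and length correction the fibroblast median was 0.52 and the cytoskeleton median 0.32. With DESeq2 the adhesion median was -2.36, but DESeq2 was run without the low-count filter, so the list members could differ.

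The replicate numbers did not pair the libraries. Residual correlations of same-numbered vehicle and colchicine libraries were -0.112, -0.159, 0.032 and -0.247, with 0 of 4 over 0.1. With the number as a block, 2305 genes changed (1121 raised, 1184 lowered) and 30 lists passed, among them neutrophil (-6.27), NADPH oxidase (-1.50), cardiac muscle (-1.45), lymph node (-0.91) and white adipocyte genes (-0.92), while 101 of the 149 named genes passed and 48 did not. Those 48 included S100a8 (adjusted p = 0.0734), S100a9 (0.112), Myh11 (0.0514), Col8a1 (0.0808), Mmp9 (0.0518) and Rps19 (0.057).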

Other observations

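Clock genes were higher in part, with 7 of 18 raised and 2 lowered (10 changed when adjusted over the list alone, median 0.772, adjusted p = 0.117). The clock output factor Hlf rose by 1.88 and Nr1d2, a repressor in the clock, by 1.78. Nfil3 at -1.90 and Bhlhe40 at -1.61 went the other way, the last named after its value was seen. Hlf passed only without vehicle 4 and not without any other library (vehicle 1, 2 or 3, or colchicine 1, 2, 3 or 4, adjusted p of 0.0637 to 0.151). Nr1d2 did not pass without vehicle 2, vehicle 3, colchicine 1, colchicine 2 or colchicine 4 (0.054 to 0.0898). With the erythroid covariate neither passed (0.104 and 0.0669), nor did Hlf without TMM factors (0.0657) or after the GC and length correction (0.0625). The circadian rhythm pathway had 12 of 28 genes raised against 4.54 by chance (adjusted p = 0.0133). Glucocorticoid response genes rose in 5 of 15 cases and fell in 3 (9 adjusted over the list alone, median 0.448, adjusted p = 0.184), with Zbtb16 at 3.30 and Lcn2 at -4.90, and had medians of 0.12 without vehicle 1 and 0.24 without colchicine 1.

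Cartilage genes fell in 5 of 11 cases and rose in 1 (7 adjusted over the list alone, median -1.62, adjusted p = 0.33), and the list passed without vehicle 4 (median -2.36, adjusted p = 0.00675). Col10a1, a collagen of hypertrophic cartilage, fell by 8.60 ± 1.53, with 170, 315, 179 and 0.492 CPM in vehicle 1 to 4 and 0.287 to 0.603 CPM in the colchicine libraries, so vehicle 4 overlapped with them. It did not pass with limma-voom (-6.77, adjusted p = 0.285).

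The raised pathway with the lowest adjusted p was herpes simplex virus 1 infection, with 140 of 416 genes raised against 67.5 by chance (adjusted p = 2.44e-17). Of these 140, 102 were zinc-finger genes, which make up 211 members of the term, and 70 zinc-finger members were raised after the GC and length correction, with the median going from 0.79 to 0.63.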
